A study of Homo sapiens with 6 samples.

How the data were processed

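Human umbilical vein endothelial cells (HUVEC, primary cells from the lining of the umbilical vein) below passage 5 were collected 72 h after transfection with a non-targeting control siRNA (siCtrl) or with 1 of 2 siRNAs against PML (siPML-1 and siPML-2), per the labels. Each condition gave 1 RNA sample, which was hybridised in duplicate, once on chip A (replicate 1) and once on chip B (replicate 2). The series therefore holds 6 Illumina BeadChip arrays in 1 colour (Cy3), in 3 groups of 2. Groups and replicate numbers were taken from the sample titles, and chip letters from the sample descriptions and the column headings. Because the duplicates are technical, the p-values below measure the spread between arrays and not the spread between cultures.

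The deposited table of non-normalized values lists 22184 probes. Its summarised signal is an intensity, from which the authors' scanner software had already subtracted background, since values below 0 occur on each array. The deposited table also gives the standard deviation of the intensity over the beads of a probe, and the count of beads behind each probe. Its detection score is a fraction between 0 and 1, per the file headers and values, and 1 minus this score was used as the detection p. In 1 deposited detection cell, for RNF149 on the siCtrl array of chip A, a letter stood in place of a number, and the score of the nearest dimmer probe was used. A second deposited table holds log2 values of 16610 probes, made by the authors with lumi 1.14.0 per the submitters' processing notes. Its column medians lay between 7.39 and 7.41. Its scale is log2-like and its columns are aligned, but the transformation, the normalization and the probe filter behind it are not given in the sources used here. Its probe identifiers were not linked to gene names, so it served as an alternative at the level of unnamed probes, and PML, the named genes and the gene lists were not run on it. The scanner software and its version are not given in the sources used here.

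The column headings of the non-normalized table call the second PML siRNA siP3, while the labels call it siPML-2. These columns were assigned to siPML-2 because it is the only PML siRNA left once siP1 is taken as siPML-1. As a check, probes of both tables were paired through the other 4 arrays (4482 probes). The siP3 columns then had a Spearman correlation of 1.0000 with the siPML-2 columns of the log2 table and of at most 0.9703 with any other column. This check rests on values, and the labels themselves do not state the link.

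The intensities were background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3, which fits a normexp model from the detection p-values, with an offset of 16 before log2. A probe was tested when its detection p was under 0.05 on both arrays of at least 1 group (12873 probes). The probe with the highest mean over the 6 arrays stood for its gene, giving 11476 genes. Probes were named from the 18189 target names in the table, updated with a RefSeq gene table of assembly GRCh38.p14 that was used for symbols only. A current symbol was matched by 16623 probes and an older synonym by 3765, and 1796 probes kept the name in the file, 29 target names having been turned into dates. Genomic positions were not used here.

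Linear models were fitted to all 6 arrays with lmFit and eBayes, so that the 3 groups shared 1 estimate of the spread. The contrasts were siPML-1 against siCtrl, siPML-2 against siCtrl and siPML-2 against siPML-1. A gene was called changed when its 2-sided limma p, adjusted by Benjamini-Hochberg over the 11476 genes, was under 0.05 and its fold was at least 1.5. Errors of log2 fold changes are the standard errors (SE) of these moderated fits, with 2 arrays per group. A gene not detected on either array of a group has only a bound there. The bound set the bright group's mean against the mean, over the arrays of the dim group, of the higher of the lowest signal among detected probes and the probe's own signal. A further test averaged the duplicates of each RNA sample (avearrays) and set the 2 PML siRNA samples against the 1 control sample, with 1 residual degree of freedom per gene and with the lone control assumed to vary like the knockdown samples.

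The comparisons, the thresholds, 41 gene lists and the rule for naming genes were fixed before the data were examined. Lists with at least 5 tested genes (38 of the 41) were tested with camera of limma at a preset inter-gene correlation of 0.01, adjusted by Benjamini-Hochberg over the lists, beside camera with an estimated correlation and fry. Named were PML, the 10 genes per direction with the largest smaller change among those changed the same way by both siRNAs and detected on all arrays, the 5 per direction for each siRNA that were also called in the direct comparison and not called the same way by the other siRNA, up to 4 changed members per list, the 3 per direction and siRNA with the largest bounds, and 13 genes fixed by name. Genes with placeholder names and genes that could reveal a donor's sex were not named. A gene outside this rule is introduced as chosen after its values were seen.

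The test was tried on simulated arrays with known answers (siPML-1 against siCtrl, 11476 genes, 200 of them changed, 20 draws). It found 8.97% of genes changed 1.5-fold, 75.5% of those changed 2-fold and 99.9% of those changed 4-fold, with a mean of 6.55 false calls per draw (5.00% of calls). The test on averaged samples found 24.9%, 93.2% and 100% of them with a mean of 20.55 false calls (11.4% of calls). In these draws both siRNAs had the same changes, and no spread between cultures was simulated. The rates therefore do not cover siRNAs or cultures that differ. They also do not cover a share of changed genes as large as the 20.7% and 20.0% called here for siPML-1 and siPML-2. A true 1.5-fold change lies on the fold threshold itself. A shift of 0.5 log2 in a list of 21 genes was found in 20 of 20 draws with the preset correlation and in 2 of 20 with an estimated one. Genes were drawn independently of each other, which favours the preset correlation, so the draws do not test lists whose genes vary together. On the real arrays the estimated correlation was 0.266 for the mitosis list and 0.1525 for DNA replication. For the NF-kB and TNF response list it was -0.0364. Chance values for comparisons that share the control arrays came from 100 simulated draws of unchanged groups.

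Alternatives covered no background correction, median scaling, an offset of 50, no filter or a stricter filter on dim probes (detection p under 0.01 on all 6 arrays), the mean of a gene's probes, a trended robust variance prior, other fold thresholds, the authors' log2 values, each array left out in turn, only the arrays of the 2 groups compared, and the chip as a block. The replicate numbers pair arrays across groups because the labels state that a number marks a shared chip. The correlation of the deviations of same-numbered arrays from their group means was -0.00139 between siCtrl and siPML-1, -0.433 between siCtrl and siPML-2 and 0.271 between siPML-1 and siPML-2. A chip effect common to the groups would make each of these positive, and those with siCtrl were not. The pairing therefore rests on the labels and is not borne out by the values. The columns of both tables were compared in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. No sample was left out.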

Results

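The series addressed what the loss of PML, the scaffold protein of PML nuclear bodies, does to gene expression in HUVEC when each of 2 siRNAs is used alone. Between 12429 and 13121 of the 22184 probes were detected per array (56.0% to 59.2%), with a median of 41 or 42 beads per probe. Median intensities lay between 19 and 27.8. Log2 values of the duplicate arrays correlated across the tested genes at r = 0.989 for siCtrl, 0.993 for siPML-1 and 0.991 for siPML-2, with median absolute differences of 0.21, 0.16 and 0.20 log2 units. The first principal component held 66.5% of the variance and set the siCtrl arrays (-43.2 and -41.4) against the siPML-1 (23.5 and 25.1) and siPML-2 arrays (19.3 and 16.8). Each condition rested on 1 RNA sample, and the small number of arrays limits the precision of every value below.

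PML itself was lower with both siRNAs on its brightest probe (840750), with a log2 fold change of -0.98 for siPML-1 (SE 0.17, 1.97-fold, limma adjusted p = 0.00151) and of -0.70 for siPML-2 (SE 0.17, 1.63-fold, adjusted p = 0.0120). The columns used for siPML-2 carry another siRNA number in their headings and were assigned by exclusion. Signals on this probe were low, at 58.7 and 45.5 in siCtrl, 21.3 and 12.5 with siPML-1 and 25 and 21.8 with siPML-2, and the siPML-1 array of chip B was not above background. The direct difference between the siRNAs was 0.27 (SE 0.17, adjusted p = 0.474). Within chip A the changes were -0.75 and -0.49, and within chip B -1.21 and -0.92. The other 2 tested PML probes were dimmer in siCtrl and did not pass the test. Their values for siPML-1 and siPML-2 were -0.20 and 0.23 (probe 2100184) and -0.10 and -0.42 (probe 3120519). In the knockdown groups probe 2100184 was not dimmer throughout, at 21.6 and 12.3 with siPML-1 and 23.2 and 34.2 with siPML-2. With the mean of the 3 probes the values were -0.43 (adjusted p = 0.104) and -0.30 (adjusted p = 0.265), and with an offset of 50 they were -0.56 and -0.42, below 1.5-fold. The call for PML, siPML-2 vs siCtrl, was also lost without siCtrl replicate 2 (-0.60, adjusted p = 0.0629) and without siPML-2 replicate 2 (-0.60, adjusted p = 0.0787), so the loss of PML was only partly measurable on these arrays.

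ITGB1, the beta subunit shared by many matrix-binding integrins, rose with both siRNAs on each of its 3 tested probes. On the brightest (2320301) the log2 fold changes were 1.17 with siPML-1 (SE 0.18, 2.25-fold, adjusted p = 0.000574) and 1.28 with siPML-2 (SE 0.18, 2.43-fold, adjusted p = 0.000332). The other probes gave 2.04 and 1.93 (5890707) and 1.67 and 2.06 (940129), while 2 further ITGB1 probes were not detected on both arrays of any group. Within single chips the rise on probe 2320301 ranged from 0.98 to 1.58.

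**Figure D1:**
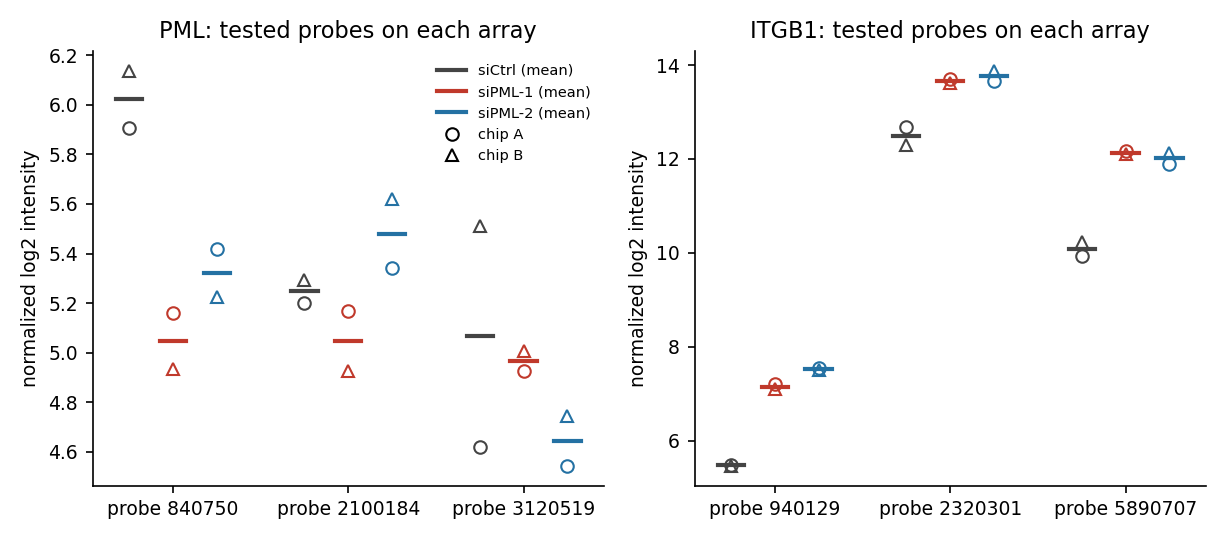
Normalized log2 intensity of the tested PML and ITGB1 probes on each of the 6 arrays by group, with circles for chip A, triangles for chip B and bars for group means. The brightest PML probe was lower in both knockdown groups by 0.98 and 0.70 log2 units on average, and each ITGB1 probe was higher.

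With siPML-1, genes of cell division rose most. CDC20, the activator of the anaphase-promoting complex, rose 46.6-fold (log2 5.54, SE 0.22, adjusted p = 1.51e-08), the PCNA-binding factor PCLAF (KIAA0101 in the file) 29.5-fold (log2 4.88, SE 0.19), the mitotic cyclin CCNB2 27.0-fold (log2 4.75, SE 0.19) and the cyclin CCNA2 23.2-fold (log2 4.54, SE 0.18). ASPM, a spindle pole protein, and KIF20A, a kinesin of cytokinesis, were not detected on either siCtrl array and were at least 24.5-fold and 22.2-fold higher. The largest falls were those of MS4A6A, a membrane protein known from myeloid cells (log2 -3.77, SE 0.18), SCG5, a chaperone of prohormone processing (-3.69, SE 0.20), CTSK, the collagen-degrading protease cathepsin K (-3.49, SE 0.16) and the cytokine IL1A (-3.47, SE 0.18), 11.1-fold to 13.7-fold lower. CD69, an early activation antigen of lymphocytes, was at least 10.5-fold lower, and its siPML-1 arrays were not well above background. Among the 11476 genes, limma called 2380 changed, 1120 up and 1260 down, of which 507 and 447 changed at least 2-fold. Of the 2380, which were selected on the same arrays, 1747 changed by at least 1.5-fold on each chip. Without siPML-1 replicate 2 the count was 1494. With an offset of 50, 66 log2 fold changes against siCtrl of called named genes and passing lists were over 1.5-fold smaller, and all 66 kept their calls. With siPML-1 they included CDC20 (4.90), PCLAF (4.0), CCNB2 (3.85), CCNA2 (3.69), MS4A6A (-3.02) and CTSK (-2.80). PCLAF was 3.03 with the mean of its probes.

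With siPML-2, the same cell division genes were again among the largest rises, CDC20 by 23.7-fold (log2 4.57, SE 0.22, adjusted p = 8.98e-08), PCLAF by 17.4-fold (4.12, SE 0.19) and CCNB2 by 14.8-fold (3.89, SE 0.19). PLSCR4, of the phospholipid scramblase family, rose 12.7-fold (3.67, SE 0.17), close to its 12.4-fold rise with siPML-1 (3.64, SE 0.17). IFIT1, an interferon-induced RNA-binding protein, was not well above background with siPML-2 and at least 15-fold lower (measured log2 -4.07, SE 0.19). CTSK fell 10.3-fold (-3.37, SE 0.16), the metallocarboxypeptidase-like CPXM1 9.14-fold (-3.19, SE 0.19), and ISG15, an interferon-induced ubiquitin-like protein, 8.13-fold (-3.02, SE 0.22). CX3CL1, the membrane-bound chemokine fractalkine, fell 7.64-fold (-2.93, SE 0.17). With an offset of 50 the values included 3.94 for CDC20, 3.27 for PCLAF, 3.02 for CCNB2, -3.00 for IFIT1 and -2.73 for CTSK, and PCLAF was 2.44 with the mean of its probes. In all, 2295 genes were called, 1150 up and 1145 down, of which 458 and 403 changed at least 2-fold. Of these, again selected on the same arrays, 1493 changed by at least 1.5-fold on each chip.

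The 2 siRNAs moved many genes together. Of the genes detected on all 6 arrays, those with the largest rises with both included IQGAP3 (log2 4.30 with siPML-1 and 3.68 with siPML-2), a scaffold of proliferating cells, CKS1B (4.45 and 3.59), a subunit of cyclin-dependent kinases, the microtubule-binding NUSAP1 (4.42 and 3.47) and PRC1 (4.16 and 3.37), and the thymidine kinase TK1 (3.83 and 2.98), with SE from 0.17 to 0.21. The largest falls with both included SH3PXD2A (-2.96 and -3.00), an adaptor of matrix-degrading podosomes, the secreted amino acid oxidase IL4I1 (-3.22 and -2.95), the interferon-induced chemokine CXCL11 (-2.99 and -2.69) and ALOX5AP (-2.75 and -2.47), which serves leukotriene synthesis, with SE from 0.16 to 0.21. Called in the same direction by both were 1567 genes, 821 up and 746 down, against 112.2 and 125.7 for independent lists of these sizes. They made up 65.8% of the siPML-1 calls and 68.3% of the siPML-2 calls. Simulated unchanged groups that shared simulated control arrays had 0 calls in common in 100 draws. These draws held array noise alone, with no deviation of the control culture. The values for independent lists leave out the shared control, and the simulation leaves out the real effects. Part or all of the excess may therefore come from the shared control sample. Across genes, which are not independent replicates, the log2 fold changes of the siRNAs correlated at r = 0.847 (Spearman rho = 0.778), against a simulated r of 0.50 and rho of 0.477. The covariance was 0.322 against a simulated 0.0211, a difference of 0.301. Between chips, with no control array in common, r was 0.597 and 0.699, and within chips A and B it was 0.858 and 0.810. The control arrays of both chips carry the same RNA sample, so the values between chips are not free of the shared control. With the authors' normalized values, 969 and 933 of 16610 unnamed probes passed the same thresholds for siPML-1 and siPML-2, against 2601 and 2505 of the 12873 probes tested here.

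**Figure D2:**
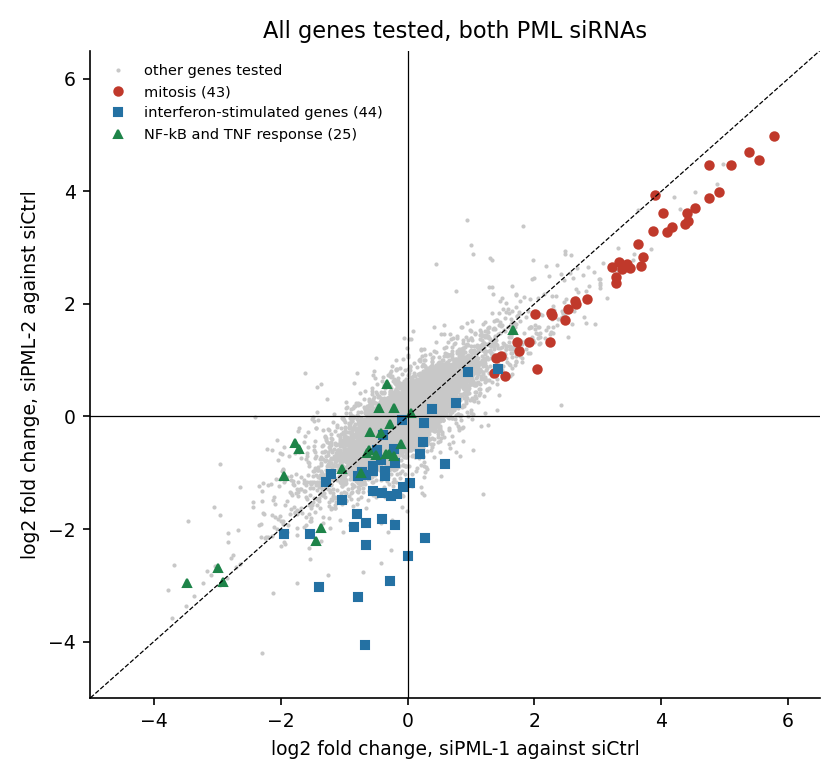
Log2 fold change against siCtrl of each tested gene with siPML-1 (x axis) and siPML-2 (y axis), with members of the mitosis list in red (43), interferon-stimulated genes in blue (44), NF-kB and TNF response genes in green (25) and all others in grey, and a dashed line where both are equal. The mitosis genes lie far up on both axes, and many interferon-stimulated genes lie below the line.

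All 43 tested genes of the mitosis list rose with each siRNA, with median log2 fold changes of 3.39 and 2.65 (camera adjusted p = 5.2e-52 and 1.4e-45). With an estimated correlation the list test gave adjusted p = 0.250 with an estimated correlation for siPML-1 and adjusted p = 0.200 for siPML-2. UBE2C, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, rose by 5.78 and 4.99 (SE 0.19), and TOP2A, the topoisomerase of mitotic chromosomes, by 5.38 and 4.70 (SE 0.18), both detected on only 1 of the 2 siCtrl arrays. For 20 members at their bound in the control the medians became 3.17 and 2.30. They were 2.42 and 1.70 with an offset of 50 and 2.65 and 1.99 with the stricter filter on dim probes. UBE2C rose by 3.22 and 2.79 with the mean of its probes. Of the 40 tested DNA replication genes, 30 rose with siPML-1 (31 adjusted over the list alone) and 28 with siPML-2 (28 adjusted over the list alone), and none fell. Their medians were 1.51 and 1.01 (camera adjusted p = 2.8e-22 and 1.4e-17), or 1.49 and 0.95 with 6 members at their bound, and adjusted p = 0.261 and 0.274 with an estimated correlation. RRM2, a subunit of ribonucleotide reductase, was at least 7.91-fold and 6.29-fold higher, GINS2, of the replicative helicase, rose by 3.01 and 2.44 (SE 0.18), and the replication licensing factor CDT1 by 2.69 and 2.22 (SE 0.20). The mitosis counts adjusted over the list alone were also 43 and 43. CDKN1A, the cell cycle inhibitor p21, did not pass the test (-0.16 and -0.25, SE 0.17).

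Of 44 tested interferon-stimulated genes, 15 fell and 4 rose with siPML-1 (median -0.39, camera adjusted p = 0.00912, adjusted p = 0.360 with an estimated correlation). With siPML-2, 35 fell and 2 rose (median -1.11, or -1.06 with 3 members at their bound, camera adjusted p = 4.8e-19, adjusted p = 0.0816 with an estimated correlation). The counts adjusted over the list alone were the same. ISG15 changed by -1.40 and -3.02 (SE 0.22) and LGALS3BP, a secreted glycoprotein, by -1.95 and -2.09 (SE 0.18). Of 17 tested genes of MHC class I presentation, 6 fell and 1 rose with siPML-1 (median -0.35, camera adjusted p = 0.0334, adjusted p = 0.415 with an estimated correlation), and 7 fell with siPML-2 (median -0.33, camera adjusted p = 0.00118, adjusted p = 0.315 with an estimated correlation). HLA-B, a classical antigen-presenting molecule, fell by 1.23 and 1.81 (SE 0.18). These counts were also unchanged adjusted over the list alone, and the siPML-1 list call was lost with the stricter filter on dim probes and without siCtrl replicate 2.

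Of 25 tested NF-kB and TNF response genes, 13 fell and 1 rose with each siRNA (median -0.60 with siPML-1 and -0.65 with siPML-2, or -0.49 and -0.49 with members at their bound). Camera gave adjusted p = 4.5e-07 and 1.3e-05, and adjusted p = 0.250 and 0.200 with an estimated correlation. Adjusted over the list alone, 13 fell with siPML-1 and 15 with siPML-2. IL1A changed by -3.47 and -2.96 (SE 0.18), PTGS2, the inducible cyclooxygenase, by -1.45 and -2.21 (SE 0.20), and PTX3, a secreted pattern recognition protein, went the other way, by 1.66 and 1.54 (SE 0.17). Of 14 tested leukocyte adhesion molecules, 1 rose and 3 fell with siPML-1, and 2 rose (3 adjusted over the list alone) and 3 fell with siPML-2, and the list passed in neither comparison (camera adjusted p = 0.236 and 0.985). For siPML-2 its median was -0.03 while its mean was 0.10. P-selectin (SELP), stored in endothelial granules, was at least 1.96-fold and 5.30-fold higher, and the junctional adhesion molecule JAM2 at least 2.83-fold and 2.88-fold lower. E-selectin (SELE) changed by -1.04 and -0.89 (SE 0.16), with calls that were lost at an offset of 50. ICAM1 did not pass the test against siCtrl (-0.56 and 0.24, SE 0.20), and VCAM1 was not detected on both arrays of any group.

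Matrix proteases and inhibitors moved in both directions, 4 up and 9 down of 24 with each siRNA, also when adjusted over the list alone (median -0.28, camera adjusted p = 0.0334, adjusted p = 0.526 with an estimated correlation for siPML-1, and median -0.31, camera adjusted p = 0.105 for siPML-2). HPSE, the heparan sulphate-cleaving heparanase, changed by -3.45 and -1.85 (SE 0.16), tissue plasminogen activator PLAT by -1.94 and -1.57 (SE 0.20), and the metalloprotease ADAMTS18 by 2.58 and 2.86 (SE 0.18). Of 16 histone genes, 4 rose and 8 fell with siPML-1 (median -0.57, camera adjusted p = 0.0915) and 2 rose and 8 fell with siPML-2 (median -0.51, camera adjusted p = 0.00839, adjusted p = 0.383 with an estimated correlation). H3-3B, which encodes a replication-independent histone, changed by -1.74 and -2.11 (SE 0.17), H2BC5 by -1.74 and -1.98 (SE 0.18), and H4C3, a histone gene of replicating cells, by 1.94 and 1.59 (SE 0.19). Of 23 genes of cholesterol synthesis and uptake, 7 rose and 1 fell with siPML-1 (median 0.23, camera adjusted p = 0.0318, adjusted p = 0.415 with an estimated correlation) and 4 rose and 2 fell with siPML-2 (median 0.04, camera adjusted p = 0.841). Of 25 NRF2 targets, 5 rose and 1 fell with siPML-1 (median 0.25, camera adjusted p = 0.0463, adjusted p = 0.415 with an estimated correlation) and 8 rose and 1 fell with siPML-2 (median 0.21, camera adjusted p = 0.0564). Haem oxygenase HMOX1 rose by 1.64 and 2.32 (SE 0.16), while the steroid-converting reductase AKR1C3 changed by -1.42 and -1.30 (SE 0.16). Of 58 cytosolic ribosomal protein genes, 4 rose with siPML-1 (median 0.15, camera adjusted p = 0.0334, adjusted p = 0.526 with an estimated correlation) and 8 with siPML-2, 7 adjusted over the list alone (median 0.22, camera adjusted p = 0.00595, adjusted p = 0.640 with an estimated correlation). Adjusted over the list alone, the histone, cholesterol, NRF2 and remaining ribosomal counts were the same. Median scaling ended the cholesterol and NRF2 calls, and 1 omitted array was enough to end each siPML-1 call of the protease, cholesterol, NRF2 and ribosomal lists and the siPML-2 calls of the histone and ribosomal lists. The lists passing against siCtrl numbered 9 for siPML-1 and 7 for siPML-2, and 4 for siPML-1 without siCtrl replicate 2. With an estimated correlation 0 passed for either siRNA, and by fry 18 passed for siPML-1 and 10 for siPML-2. Of the lists that passed by camera against siCtrl, the ribosomal list alone did not pass by fry (adjusted p = 0.0896 and 0.0818). The fry adjusted p was 0.00117 and 0.00154 for mitosis and 0.0170 and 0.000890 for interferon-stimulated genes. For the NF-kB and TNF response list it was 0.000211 and 0.000127.

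**Figure D3:**
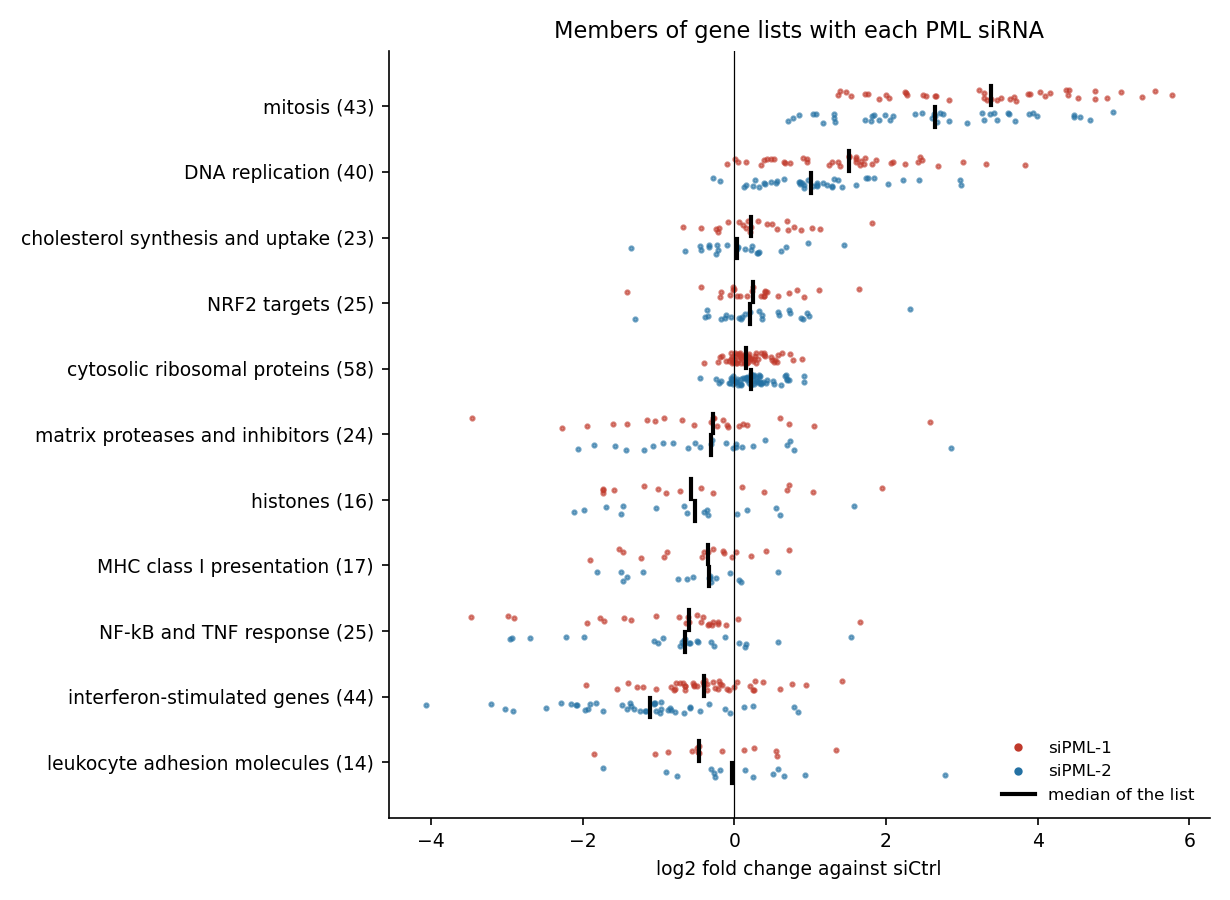
Log2 fold change against siCtrl of each tested member of the 11 lists that passed in at least 1 comparison, with siPML-1 in red, siPML-2 in blue and a black bar at each list's median. The mitosis medians of 3.39 and 2.65 stand apart from those of the other lists, and interferon-stimulated genes lie lower with siPML-2 (median -1.11) than with siPML-1 (median -0.39).

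In the direct comparison of the siRNAs, MX1, an interferon-induced antiviral GTPase, was lower with siPML-2 than with siPML-1 by a log2 difference of -2.65 (SE 0.21, adjusted p = 4.9e-05), with -0.28 for siPML-1 and -2.92 for siPML-2 against siCtrl. The interferon-induced EPSTI1 (-2.48, SE 0.18) and IFI44L (-2.42, SE 0.16) and the atypical chemokine receptor ACKR3 (-2.18, SE 0.16) were lower as well, and IFIT1 was at least 9.42-fold lower. The chemokine CCL23 was higher with siPML-2 (2.26, SE 0.16), having changed by 0.46 and 2.72 against siCtrl, and HBQ1, of the globin family, differed by 1.43 (SE 0.19). Lower with siPML-2 after a rise with siPML-1 were TMSL8, a thymosin (-2.22, SE 0.20), the replication fork protein TIMELESS (-1.41, SE 0.16) and the lipid raft protein FLOT1 (-1.28, SE 0.17). CXCL1, a neutrophil-attracting chemokine, fell with siPML-1 (-1.77, SE 0.16) and did not pass the test with siPML-2 (-0.47), a difference of 1.30 (SE 0.16). The siCtrl mean cancels from this contrast, while the siCtrl arrays took part in the normalization and in the estimate of the spread. In all, 554 genes were called, 280 higher and 274 lower with siPML-2, and 145 of the 1567 genes that both siRNAs moved the same way were among them. Of the interferon-stimulated genes, 23 were lower and none higher (24 adjusted over the list alone), with a median of -0.67 (camera adjusted p = 2.5e-26, adjusted p = 0.0494 with an estimated correlation). Mitosis genes were also lower with siPML-2 than with siPML-1, 20 of 43 by call (32 adjusted over the list alone), with a median of -0.74 (camera adjusted p = 2.1e-24, adjusted p = 0.473 with an estimated correlation). The number of mitosis genes called was 12 with the chip as a block, 4 with median scaling, 8 with no filter on dim probes and 5 with the stricter one. It was 3 without siPML-1 replicate 1, 0 without siPML-1 replicate 2 and 3 without siPML-2 replicate 2. DNA replication genes followed with 7 lower (8 adjusted over the list alone, median -0.40, camera adjusted p = 4.6e-08, adjusted p = 0.474 with an estimated correlation), and cholesterol genes with 4 lower (4 adjusted over the list alone, median -0.20, camera adjusted p = 0.00177, adjusted p = 0.473 with an estimated correlation). Of the leukocyte adhesion molecules 3 were higher (3 adjusted over the list alone, median 0.19, camera adjusted p = 0.00644, adjusted p = 0.473 with an estimated correlation). By fry the interferon list passed (adjusted p = 0.00502). The NF-kB and TNF response list passed by fry (adjusted p = 0.0274) and not by camera (adjusted p = 0.299). The mitosis, DNA replication, cholesterol and leukocyte adhesion lists did not pass by fry (adjusted p = 0.0779, 0.0945, 0.0779 and 0.0945). The number of genes changed siPML-2 vs siPML-1 was 262 with median scaling, 358 with no filter on dim probes and 159 probes with the authors' values, and it fell to 119 without siPML-1 replicate 1, 102 without siPML-1 replicate 2, 357 without siPML-2 replicate 1 and 255 without siPML-2 replicate 2.

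With the duplicates averaged, the 2 PML siRNA samples were set against the single control sample. The log2 differences were 3.65 for PLSCR4, -3.43 for CTSK, -3.28 for CPXM1, -2.98 for SH3PXD2A, 1.23 for ITGB1 and -0.84 for PML. The control has no spread of its own in this test, so no call is given for a single gene. The smallest limma adjusted p was 0.00918. The count was 413 genes, 262 up and 151 down, and it does not speak to how control cultures vary. Its spread comes from the difference between the siRNAs and favours genes that both moved alike. On simulated arrays, where both siRNAs had the same changes and cultures did not vary, 11.4% of its calls were false. The number of genes changed by PML siRNA at the sample level was 624 (330 up and 294 down) with median scaling, 264 with an offset of 50, 0 with no filter on dim probes and 0 with the authors' values, and it fell to 218 without siPML-1 replicate 1 and to 258 without siPML-2 replicate 1.

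Among the genes fixed by name, glyceraldehyde phosphate dehydrogenase (GAPDH, -0.01 and -0.01), beta-actin (ACTB, -0.02 and 0.00) and the junctional cadherin CDH5 (0.01 and 0.08) did not pass the test (SE 0.16 to 0.17). The receptor KDR (-0.14 and 0.23), the nitric oxide synthase NOS3 (0.26 and -0.06) and the PML body proteins SP100 (0.07 and 0.05) and DAXX (0.09 and -0.01) did not pass the test either. All 30 endothelial identity genes on the array were detected on both siCtrl arrays. Markers of other cell types were mostly below detection in the control, with 3 of 17 leukocyte, 2 of 15 fibroblast, 2 of 13 erythroid and platelet, 6 of 17 smooth muscle and pericyte and 5 of 16 epithelial markers detected on both arrays. Of the markers of lymphatic endothelium, 11 of 13 were detected on both. Among the markers of other cell types CORO1A, an actin-binding protein of leukocytes, was lower with both siRNAs (-1.18 and -1.28, SE 0.18), as were the fibroblast proteoglycan LUM (-2.04 and -1.82, SE 0.25), the tight junction protein CLDN7 (-1.98 and -0.98, SE 0.20) and the keratin KRT8 (-0.78 and -0.83, SE 0.20), both known from epithelia. The fibroblast matrix protein FBLN1 was higher with both (0.75 and 0.75, SE 0.19). The KRT8 and FBLN1 calls were lost with an offset of 50. The call for KRT8, siPML-1 vs siCtrl, was also lost without siPML-1 replicate 1 (-0.48), and both FBLN1 calls without siCtrl replicate 2 (0.54 for FBLN1, siPML-1 vs siCtrl, and 0.53 for FBLN1, siPML-2 vs siCtrl), the former also without siPML-1 replicate 2 (0.67) and the latter without siPML-2 replicate 1 (0.65).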

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

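The tests of the single control culture, of PML depth and of siRNA sequence were chosen after the results were seen, and the tests of normalization, chip and leukocyte content were set beforehand.

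All 43 tested mitosis genes were higher with both PML siRNAs. The prediction for normalization between arrays was a list median below 1.5-fold under some setting. The lowest median over the 4 normalizations run and both siRNAs was 1.70 on the log2 scale. This argues against the choice among these 4 and does not cover other normalizations. The lowest median over both chips was 2.61. Each chip held all 3 groups, so a difference common to a chip's arrays cancels from these contrasts by design. The state of the single control culture, for the rise common to both siRNAs, cannot be told apart from an effect of PML loss, because 1 control RNA sample was grown and a slowly dividing control culture could give the same rise. PML loss stays a hypothesis for the common rise.

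Interferon-stimulated genes were lower with siPML-2 than with siPML-1. The highest median difference over the 4 normalizations run was -0.61, which argues against the choice among these 4. Deeper loss of PML with siPML-2 would have been excluded by the first criterion, 1 standard error, since PML differed by 0.27 (SE 0.17) in the other direction. The criterion was changed after the values were seen, to ask for the same direction on all tested PML probes, and as the other probes differed by 0.43 and -0.32 (SE 0.18 and 0.24) near background, the explanation stays open. An effect of an siRNA sequence other than through PML cannot be told apart from an effect of PML loss, as 2 sequences were compared and a list that differs between them may follow either sequence.

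Genes known from leukocytes, CD69, MS4A6A and ALOX5AP, were lower with both siRNAs, and leukocytes in the control culture could carry them. Of 17 leukocyte markers, 1 (CORO1A) was called lower with both, 3 were detected on both control arrays and 10 on neither, the abundant LCP1 among the latter. The bound set beforehand also asked that PTPRC and LYZ be undetected in the control, and each was detected on 1 of the 2 arrays. Neither was rarer after knockdown, with PTPRC detected on 1 siPML-1 array and 2 siPML-2 arrays and LYZ on 1 and 1. The markers CD14 and CSF1R were each detected on 1 siCtrl array and on 0 arrays with either PML siRNA. SPI1 was detected on 2 siCtrl, 1 siPML-1 and 2 siPML-2 arrays, and CD3E on 0, 1 and 0. The levels of PTPRC, LYZ, CD14, CSF1R, SPI1 and CD3E were close to background and decide nothing. CD68 and CORO1A were brighter, at 9.21 and 6.85 log2 in siCtrl. CORO1A fell with both siRNAs. With 1 array left out in turn, CD68 changed by -0.0028 to 0.156 with siPML-1 and by -0.91 to -0.49 with siPML-2. As these 2 markers differ, leukocytes in the control culture cannot be told apart from a change within the endothelial cells.

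The direct comparison, which tested for a difference between the siRNAs, called 554 genes. It set 1 RNA sample against 1 other by the spread of technical duplicates, and without siPML-1 replicate 2 it called 102. The lists that differed in it had median log2 differences (siPML-2 minus siPML-1) of -0.67 for interferon-stimulated genes, -0.74 for mitosis, -0.40 for DNA replication, -0.20 for cholesterol synthesis and uptake and 0.19 for leukocyte adhesion molecules. With an estimated correlation only the interferon list passed (adjusted p = 0.0494), and the others had adjusted p = 0.473, 0.474, 0.473 and 0.473 with an estimated correlation and did not pass by fry. Called in opposite directions against siCtrl were 9 genes, of which 8 can be named here; they were chosen after their values were seen. The gap junction gene GJA4, of arterial endothelium, rose 2.29-fold with siPML-1 and fell 2.60-fold with siPML-2, a difference of -2.58 (SE 0.18, adjusted p = 2.0e-05), and it kept its calls in each alternative run. LYVE1, a hyaluronan receptor of lymphatic endothelium, differed by 2.39 (-1.61 and 0.78), SERTAD2 by 1.57 (-0.79 and 0.78) and GABBR2 by 1.43 (-0.84 and 0.59). Lower with siPML-2 were CCNA1 (-1.53, from 0.83 and -0.70), IFI35 (-1.45, from 0.60 and -0.85), HMGB3 (-1.43, from 0.59 and -0.84) and OLFML2A (-1.39, from 0.76 and -0.63). For these 7 genes at least 1 of the calls against siCtrl was lost when an array was left out, and the siPML-2 calls of GABBR2 and OLFML2A were also lost with the chip as a block.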

How the results depend on the processing

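The crossed pairing below was chosen after the data were seen, and all other alternatives were fixed beforehand. Calls against siCtrl held best. The 2380 genes changed siPML-1 vs siCtrl, the 2295 genes changed siPML-2 vs siCtrl and the 1567 genes changed the same way by both siRNAs stayed within 1.5 times under no background correction, median scaling, an offset of 50, both filters on dim probes, the mean of probes, a trended robust variance prior and fits of 2 groups alone. With the chip as a replicate block, for the pairing by chip, they were 2290, 2192 and 1501 with 378 genes changed siPML-2 vs siPML-1, and 9, 7 and 5 lists passed. The block ended the siPML-1 calls of IFITM1 and HSF1, the siPML-2 calls of ROCK1, MVK, PHGDH, SNAI1, GABBR2 and OLFML2A, and the direct calls of CDC20, PCLAF, CCNB2, CCNA2, TK1, SP110, PMAIP1, HMOX1, TFF3, LAYN and ICAM1, and it changed no other call of a named gene from past to short of the threshold. With the siCtrl numbers exchanged the counts were 2441, 2360, 766 and 1606. Median scaling gave 262 direct calls and 624 genes changed by PML siRNA at the sample level. An offset of 50 gave 264 at the sample level and PML values of -0.56 and -0.42. No filter on dim probes gave 358 direct calls and 0 at the sample level. The mean of probes gave PML values of -0.43 and -0.30 and turned TNFRSF10B, siPML-1 vs siCtrl, to -0.0064. A 2-fold minimum left 954, 861, 183 and 595 genes (siPML-1, siPML-2, direct, shared), and treat left 1487, 1375, 164, 935 and, at the sample level, 246. The authors' values gave 969, 933, 159, 613 and 0 probes, while 2456, 2313 and 369 passed on adjusted p alone. Duplicates treated as separate arrays gave 2229 in place of 413. Lists passing for siPML-1, siPML-2 and the direct comparison were 0, 0 and 1 with an estimated correlation, and 18, 10 and 2 by fry. The correlation of the siRNAs was 0.810 within chip B. Leaving out 1 array at a time gave 1494 to 2689 genes for siPML-1, 1905 to 2271 for siPML-2, 102 to 757 direct, 1166 to 1626 shared and 218 to 512 at the sample level, 4 to 13, 5 to 7 and 4 to 7 lists, r from 0.806 to 0.860 and PML from -1.08 to -0.88 and from -0.81 to -0.60. A lone remaining array was assumed to vary like the other groups. Under the stricter filter PML was not tested. For the named genes each comparison was counted once per setting. Of these results, 398 in the other alternatives and 268 with an array left out fell short of the threshold. Meanwhile 31 and 32 came to pass it, and 6644 and 3300 stayed the same. The 398 include 141 from the 2-fold minimum and 99 from treat. Higher thresholds and fewer tested genes lower counts by construction, and for the other changes the cause was not tested. PML lies close to background, which limits how well its loss can be measured.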

Other observations

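Genes of cell attachment and matrix changed in both directions with both siRNAs. The laminin chain LAMC1 rose by 2.84 with siPML-1 and 2.66 with siPML-2 on the log2 scale (SE 0.16, adjusted p = 2.2e-07 and 5.1e-07), while the matrix protein TGFBI changed by -2.20 and -2.13 (SE 0.17) and the basement membrane protein NID2 by -1.79 and -1.60 (SE 0.25). Among 17 tested integrins 2 rose and 6 fell with siPML-1 and 1 rose and 4 fell with siPML-2. The collagen-binding subunits ITGA1 (-1.38 and -1.62, SE 0.17) and ITGA11 (-1.48 and -1.45, SE 0.16) fell, opposite to ITGB1. Neither the integrins (camera adjusted p = 0.410 and 0.309) nor the 31 genes of extracellular matrix and basement membrane (0.862 and 0.743) passed as a list. The arterial receptor NOTCH4 changed by -1.97 and -1.85 (SE 0.16) and the Notch target HEY1 by -1.15 and -1.63 (SE 0.17), within a Notch and sprouting list of 29 in which 10 fell and 2 rose with siPML-1 (camera adjusted p = 0.0799) and 5 fell and 1 rose with siPML-2 (camera adjusted p = 0.420, median 0.02 and mean -0.21). The tight junction protein CLDN5 fell by 0.98 and 1.18 (SE 0.19), and KLF2, a flow-responsive transcription factor of endothelium, rose by 1.96 and 2.45 (SE 0.17).

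The receptor tyrosine kinase AXL rose by 1.67 and 1.60 (SE 0.21) and the transcription factor TEAD4 by 1.22 and 1.28 (SE 0.18), and the stress-induced ATF3 changed by -1.37 and -1.24 (SE 0.18). The chaperone DNAJB9 changed by -1.75 and -1.73 (SE 0.19) while MANF, another protein of the endoplasmic reticulum stress response, rose by 1.13 and 1.25 (SE 0.17). CPT1C, of the carnitine palmitoyltransferase family, changed by -1.60 and -1.94 (SE 0.18), and ACADM, an enzyme of fatty acid oxidation, rose by 1.25 and 1.52 (SE 0.18). The proapoptotic PMAIP1 changed by -2.35 and -1.23 (SE 0.26). In all, 27 lists passed in no comparison, these of matrix, Notch and integrins included, with lowest camera adjusted p of 0.0799 for siPML-1, 0.222 for siPML-2 and 0.105 for the direct comparison. The 3 lists with fewer than 5 tested genes (fibroblast, leukocyte, and erythroid and platelet markers) were not tested.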
